A study of Mus musculus with 8 samples.

How the data were processed

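The samples were 8 ATAC-seq libraries of the right striatum of C57BL/6 mice, 4 sham-operated and 4 with BCAS, grouped by the treatment in the labels. Per the labels' protocols, nuclei were transposed with Tn5 and the libraries sequenced as paired-end reads. Per the submitters' processing notes, the tools were FastQC, Bowtie2, SAMtools 1.9, MACS2, DiffBind, ChIPseeker and HOMER and the build was mm10; their roles, parameters, read shifting and duplicate removal were not given in the sources used here. The authors deposited 1 list of narrow peaks per library, so peaks were called per library and not on pooled samples. Each deposited line gives a peak's interval, a score, its summit, a fold enrichment (the authors' ratio of pileup to expected background), and the -log10 of its p-value and of its q-value. These fold enrichments, -log10 p-values and scores were the authors' own values per peak and were used here only to rank or filter peaks within a list. The smallest -log10 q-value in each deposited list was close to 1.3, the value of a q of 0.05, so weaker signal was not listed and a missing peak does not show closed chromatin.

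The lists give no read totals. The pileup at each summit was recovered from the deposited fold and -log10 p-value under the caller's published formulas, for peaks with a -log10 p-value under 280, and it was whole within 0.05 for 100% of peaks in each library. The most frequent background pileup was 2.52, 1.52, 1.55 and 1.62 in Sham 1 to 4 and 1.41, 2.01, 2.73 and 1.65 in BCAS 1 to 4 (exact permutation p = 0.657). It was taken as a relative measure of depth, and how it bears on the smallest enrichment called was not tested. The median summit pileup was 17 to 24 in Sham and 19 to 27 in BCAS libraries.

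Because list length differed, each list was shortened to its 72548 peaks of highest -log10 p-value, the length of the shortest list. Regions were unions of overlapping peaks (1 bp or more) over the 8 lists. Peaks per gene were counted by midpoint over the gene and 5 kb on both sides, since the annotation used gave no strand, for 21887 protein-coding genes of the GRCm38.p6 assembly, the same coordinates as mm10. For the same reason a window of 1 kb around either gene end took the place of the promoter, and gene interior and between genes took the place of exon, intron and intergenic classes. Of 393 listed genes, 391 were found by symbol, and the values of some of them are not reported here. A test of transcription factor motifs that had been planned was not run, because no genome sequence was used here.

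Group means were compared by two-sided exact permutation over the 70 assignments of 4 of 8 libraries, with a smallest p of 0.0286, and adjusted by the Benjamini-Hochberg method over lists, chromosomes or classes. Counts of regions and genes were set against the other 34 splits. Each list's difference was also ranked among 10000 random lists matched on the mean number of peaks: it reached percentile 100 for the homeostatic, activated, complement and NF-kappa-B lists, 99.4 for reactive astrocytes, 98.7 for interferon response, 94 for leukocytes, 88.9 for endothelial cells and 0.83 for the direct pathway. The named regions were the 10 per direction of highest median rank, and the named genes the 10 per direction with non-overlapping counts and the largest difference of means. From each list, members with non-overlapping counts or with a gene-end peak in all 4 libraries of one group and at most 1 of the other could be named, or otherwise the member with the largest difference in each direction. The groups, lists, tests, naming rule and most alternatives were set before the data were examined; the gene length classes, the enrichment and symbol family tests and the added alternatives were not. Alternatives were the lists as deposited, peaks with a -log10 q-value of 5 or more, 36274 peaks per list, other overlaps and windows, each library left out, and the replicate number as a block.

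The counting steps were tested on simulated data. With 200 of 144636 regions present in 95% of the libraries of one group and 5% of the other, 64% were called in the right direction. Before any region was changed, the simulated data gave 366 calls. With 200 genes changed, 26% of those changed 2-fold and 72.5% of those changed 4-fold were recovered. These 200 were drawn only from genes above a lower limit on mean peak number, so recovery at genes with few peaks was not measured. Before any gene was changed, the 2 simulations gave 183 and 194 calls among 17614 genes. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.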

Results

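Chromatin accessibility was profiled by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in nuclei of the right striatum of C57BL/6 mice. A group of 4 libraries came from mice after bilateral carotid artery stenosis (BCAS), a narrowing of both carotid arteries used to model chronic low blood flow to the brain. The other 4 came from sham-operated mice, and all 8 carried the same time label of 14 weeks. The comparison asked how striatal chromatin, including that of microglial and immune genes, differed after the stenosis. The peak lists held 92604, 73267, 72548 and 97059 peaks in Sham 1 to 4, and 112339, 82185, 83864 and 90203 in BCAS 1 to 4. The labels did not say whether each library was a separate animal, so p-values measured only the spread between these samples, which may be technical. Peaks were called in each library separately, and every list was shortened to its 72548 strongest peaks before regions and genes were compared.

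More regions had peaks in BCAS libraries alone than in Sham libraries alone. Of 144636 regions with a peak in any library, 5994 had a peak in all 4 BCAS libraries and no Sham library, and 1149 showed the reverse. BCAS-specific regions thus made up 83.9% of these calls, against 91.4% on the lists as deposited and 94.2% at a stricter threshold. In the latter settings list length was not matched, and BCAS lists were longer on average, which can raise this share. The best-ranked BCAS-specific region lay inside Slc9a9, which encodes an endosomal sodium-proton exchanger, on chromosome 9 from 95180212 to 95181011 (mm10). Another lay inside Naip2, a sensor of bacterial proteins, on chromosome 13 from 100183030 to 100183582, and a region on chromosome 11 from 71251283 to 71251896 lay 9076 bp from the inflammasome gene Nlrp1b. The best-ranked Sham-specific region, on chromosome 2 from 138446476 to 138447091, lay between genes, and the next, on chromosome 13 from 98156544 to 98157190, lay inside Arhgef28. On the lists as deposited 7 of the 10 named BCAS-specific regions and 2 of the 10 named Sham-specific regions kept a peak in 4 against 0 libraries, and those in Slc9a9, in Arhgef28 and on chromosome 2 did not. Gene ends held 6.64% of BCAS-specific regions, 1.83% of Sham-specific regions and 36.5% of the 27130 regions found in all 8 libraries. Gene interiors held 51.1% of the BCAS-specific and 47.6% of the Sham-specific regions. The annotation used gave no exons, so interior regions could not be divided into exonic and intronic ones. Of the 35 ways to split the 8 libraries into 4 and 4, the real one gave the most regions, 7143, and the next gave 666. The Sham-specific count was 662 on the lists as deposited and 412 at the stricter threshold, and both counts were lower with 36274 peaks per list, at 3096 BCAS-specific and 642 Sham-specific regions. Most of the 1149 Sham-specific regions overlapped a peak that shortening had removed from a BCAS list. Without Sham 1, Sham 2, BCAS 1 or BCAS 4 the Sham-specific count was 1854, 1916, 1874 or 1920, as a requirement on fewer libraries is met more often.

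**Figure D1:**
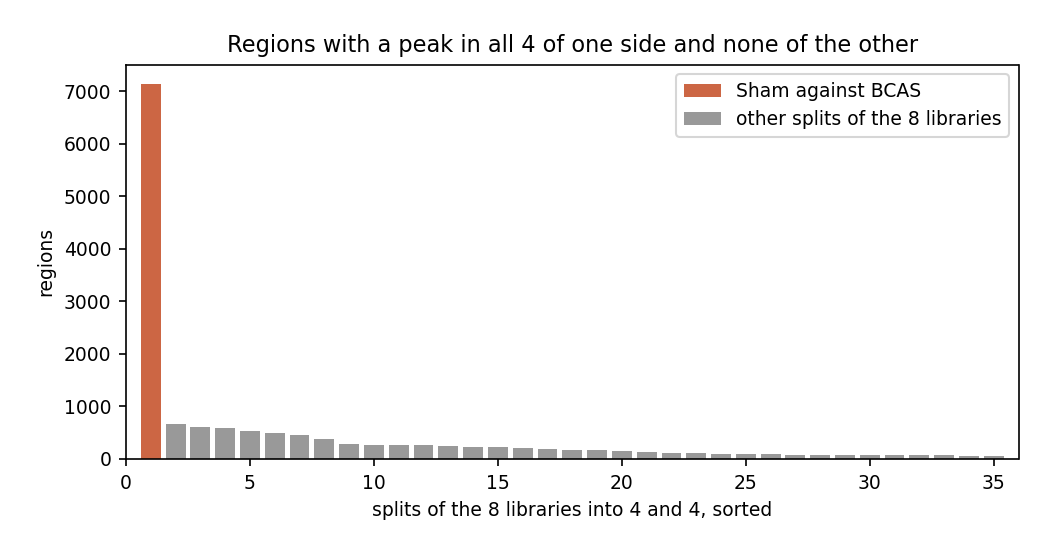
Number of regions with a peak in all 4 libraries of one side and none of the other (vertical axis) for each of the 35 splits of the 8 libraries, sorted by size. The split into Sham and BCAS gave 7143 regions and the largest of the other splits gave 666.

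At the level of genes, 1203 protein-coding genes had more peaks in every BCAS library than in any Sham library, and 258 had fewer, among 17614 genes with a peak. Lyn, a Src-family kinase of myeloid cells, held 0.5 ± 1 peaks in Sham and 14.3 ± 2.06 in BCAS (SD, n = 4). It spans chromosome 4 from 3678068 to 3791612. Fli1, an ETS-family transcription factor, held 1.75 ± 1.71 and 14.5 ± 2.89 peaks, and Etv6, of the same family, held 8.75 ± 1.71 and 25.3 ± 4.79. Rad51b, a homologous recombination gene, had the largest difference of means, from 16 ± 2.16 to 35.3 ± 8.58 peaks. It was followed by Frmd4a, with 25.5 ± 2.38 and 43 ± 6.06 peaks. The other genes with the largest differences were Itpr2, an inositol trisphosphate receptor, Hivep3, the cadherin gene Cdh23, the Notch coactivator gene Maml2 and Vps13d, with differences of 12.8 to 14.3 peaks. A peak within 1 kb of a gene end was present in all 4 BCAS and no Sham libraries for 260 genes, and the reverse held for 12. The count of 12 was 4 on the lists as deposited and 5 at the stricter threshold, and it was 25, 28 or 19 without Sham 1, 2 or 3 and 25, 24, 21 or 33 without BCAS 1, 2, 3 or 4. The real split separated 1461 genes and the highest of the other splits 235. By a two-sided exact permutation test per gene, 1461 genes had an unadjusted p of 0.0286, the smallest the design allows, and 0 passed 0.05 after Benjamini-Hochberg adjustment over all genes tested, the smallest adjusted p being 0.344. Higher calls made up 82.3% of the total, against 97.1% on the lists as deposited and 98.5% at the stricter threshold. In those settings list length was not matched, and longer BCAS lists can raise the share of higher calls. The stricter lists held 55429 to 77815 peaks in Sham and 70506 to 99571 in BCAS libraries. Of the 1203 higher genes, 943 were also called on the lists as deposited, 1106 at the stricter threshold and 496 with 36274 peaks per list.

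**Figure D2:**
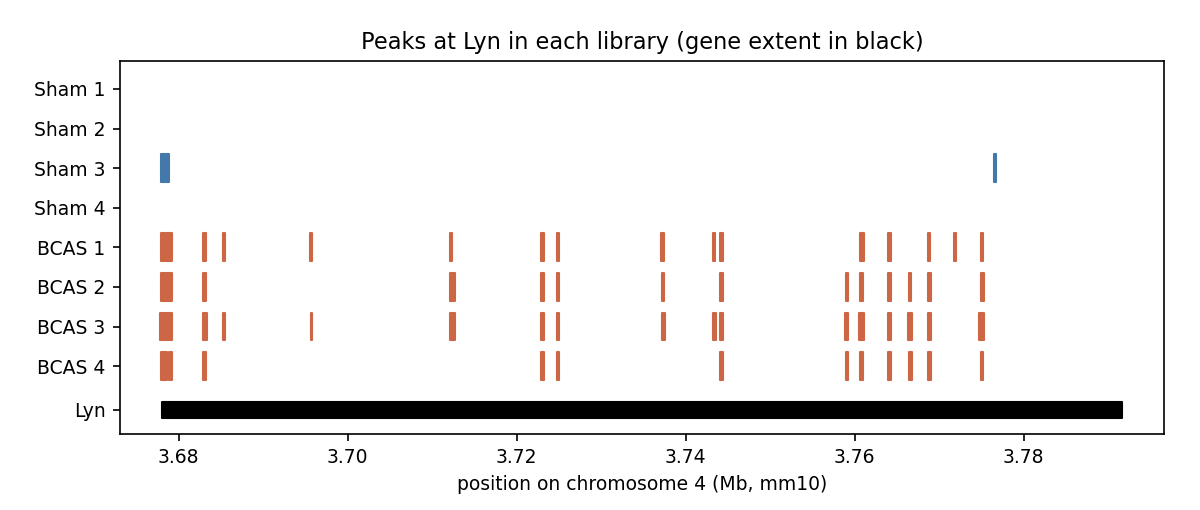
Peaks at Lyn on chromosome 4 in each library's list of 72548 peaks, by position in Mb (mm10), with Sham in blue, BCAS in orange and the gene's extent in black. Each BCAS library held 12 to 16 peaks in the gene and its 5 kb flanks, and Sham 3 was the single Sham library with any, at 2.

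Genes of homeostatic microglia, the resident macrophages of the brain, held more peaks after BCAS, at 94.5 ± 13.5 over the list against 30.8 ± 2.63 in Sham (SD, n = 4), or 3.07 times as many. Of its 21 genes, 14 had more peaks in every BCAS library than in any Sham library, 0 had fewer and 7 overlapped. Tmem119, a microglial surface marker, had 1 peak in each BCAS library and 0 in each Sham library. Cx3cr1, the fractalkine receptor, went from 0.25 ± 0.5 to 3.75 ± 0.5 peaks, and P2ry12, a purinergic receptor of microglia, from 2.5 ± 1.73 to 8.75 ± 0.957. Among transcription factors, Spi1, which encodes PU.1, held 2.5 ± 0.577 and 8 ± 0.816 peaks, and Runx1 held 4.5 ± 1.29 and 16.3 ± 3.86. Aif1, which encodes the microglial protein IBA1, held 3 peaks in each BCAS library and 0 in each Sham library. Csf1r, the receptor for microglial survival signals, overlapped in peak number (1.75 ± 0.957 and 4.75 ± 1.26) but had a gene-end peak in 4 BCAS and 0 Sham libraries. The list's exact permutation p was 0.0286, the smallest possible, and 0.0667 after adjustment over 21 lists. Adjusted over the list alone, 14 genes passed 0.05 by the exact permutation test, and adjusted over all genes tested 0 passed.

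Genes of activated or disease-associated microglia held 70.8 ± 14.2 peaks in BCAS and 35 ± 3.92 in Sham (SD, n = 4), with 9 of 22 higher in every BCAS library and 0 lower. Trem2, a lipid-sensing receptor, held 3 peaks in each BCAS library and 0 in each Sham library, and its adaptor gene Tyrobp held 4 ± 0.816 against 1. Spp1, which encodes osteopontin, and Cst7, which encodes cystatin F, each held 2 peaks in every BCAS library and 0 in every Sham library. The chemokine genes Ccl3 and Ccl4 held 1.75 ± 0.5 and 3.75 ± 0.5 peaks in BCAS and 0 in Sham, in windows that overlap each other. Complement and antigen presentation genes held 57.3 ± 9.29 peaks against 19 ± 0.816, with 12 of 22 higher and 0 lower. Among them were the complement receptor gene C5ar1 (4.75 ± 0.5 against 0), the integrin genes Itgam (3.75 ± 0.5 against 0) and Itgb2 (7.25 ± 1.71 against 1 ± 0.816), and Ciita, the class II transactivator (3.25 ± 1.89 against 0.25 ± 0.5). Genes of inflammatory cytokine and NF-kappa-B signalling held 75 ± 8.08 peaks against 40.5 ± 3.42, with 11 of 26 higher and 0 lower. Nlrp3, an inflammasome sensor, held 4.5 ± 1.29 against 0.25 ± 0.5 peaks, Tgfb1 held 5 ± 0.816 against 1 ± 0.816, and Tlr2 held 3 against 0.5 ± 0.577. These 3 lists also had an exact permutation p of 0.0286 and an adjusted p of 0.0667, and for the activated list the exact p was 0.0571 without Sham 1, 2 or 3. Adjusted over the list alone, 0 genes of any of the 3 passed 0.05, and adjusted over all genes tested 0 passed. In an enrichment test chosen after the data were seen (one-sided Fisher's exact test against the 17614 genes, adjusted over 21 lists), genes higher in BCAS were overrepresented in the homeostatic (adjusted p = 6.93e-11), activated (3.63e-05), complement (3.49e-08) and NF-kappa-B (3e-06) lists. This enrichment test takes genes as independent units, but all calls came from the same libraries, 4 per group. Its p-values therefore do not measure the spread between libraries. Neighbouring genes can share peaks, and 321 of the 1203 higher genes had a window that met that of another.

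**Figure D3:**
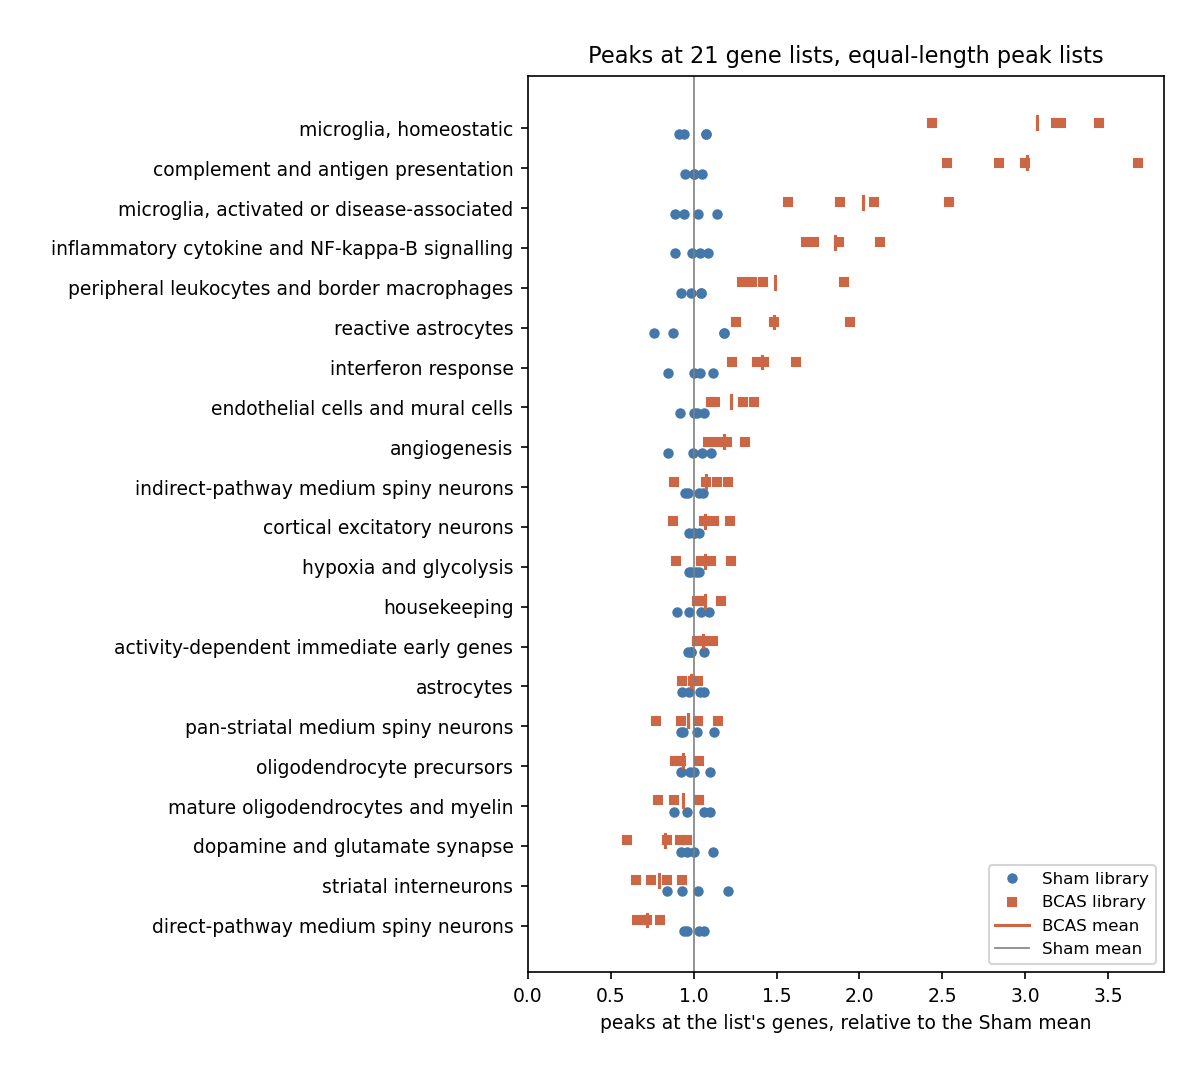
Number of peaks at the genes of each of 21 lists, relative to the Sham mean (horizontal axis), with 1 point per library, circles for Sham, squares for BCAS and a tick for the BCAS mean. The homeostatic microglia list stood at 3.07 times the Sham mean and the direct-pathway list at 0.719 times.

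Lists of other immune, glial and vascular cells showed smaller differences. Peripheral leukocyte and border macrophage genes held 24.3 ± 4.57 peaks in BCAS and 16.3 ± 0.957 in Sham (SD, n = 4), with 3 of 19 higher, namely Cd79a, Mrc1 and Klrb1c. Interferon response genes held 36.8 ± 4.11 against 26 ± 2.94, with 1 of 20 higher, Usp18 (4.75 ± 0.5 against 2.25 ± 0.5). Reactive astrocyte genes held 39 ± 8.49 against 26.3 ± 5.62, with Cp and Tgm1 higher, and endothelial and mural genes held 57.5 ± 5.92 against 47 ± 2.94, with the vascular growth factor receptor gene Flt1 higher (7.25 ± 0.5 against 3). These 4 lists had an exact permutation p of 0.0286 and an adjusted p of 0.0667. Counted in gene bodies alone, the difference was 2.5 peaks for leukocyte genes (exact p = 0.143) and 9 for reactive astrocyte genes (exact p = 0.143). On the lists as deposited it was 17.5 for reactive astrocyte genes (exact p = 0.0571), and with 36274 peaks per list 6.5 for endothelial and mural genes (exact p = 0.114). Without 1 library the exact p rose to 0.0571 for leukocyte genes (Sham 2) and interferon genes (Sham 1, 3 or 4). It rose to 0.0857 for reactive astrocyte genes (Sham 1, Sham 2 or BCAS 3) and for endothelial and mural genes (Sham 1 or 2). Astrocyte genes held 73.3 ± 2.99 and 74.3 ± 4.57 peaks (exact p = 0.743), mature oligodendrocyte genes 74 ± 9.8 and 79.3 ± 7.72 (exact p = 0.429), and oligodendrocyte precursor genes 84.3 ± 5.97 and 90 ± 6.68 (exact p = 0.314). For angiogenesis genes the values were 64.3 ± 5.12 and 54.3 ± 6.02 (exact p = 0.0571), with Notch1 and Aplnr higher in every BCAS library. Hypoxia and glycolysis genes held 70.5 ± 9.15 and 66 ± 1.83 peaks (exact p = 0.429), with the hexokinase gene Hk2 (5.5 ± 1.29 against 2.5 ± 0.577) and Pfkfb4 higher. Immediate early genes held 57.8 ± 2.36 and 54.8 ± 2.22 (exact p = 0.171) and housekeeping genes 44 ± 2.71 and 41.3 ± 3.5 (exact p = 0.371), BCAS first in each pair. Of the 20 housekeeping genes, 1 was higher in every BCAS library.

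Genes with fewer peaks in BCAS were long, with a median length of 171930 bp against 26325 bp for those with more and 22437.5 bp for all genes tested. Not every long gene had fewer: Rad51b, of 550979 bp, and Frmd4a, of 596394 bp, had more peaks in every BCAS library. Ctnna2, a neuronal catenin, went from 57 ± 3.46 peaks in Sham to 31.5 ± 12 in BCAS (SD, n = 4). The adhesion gene Tenm2 went from 54.3 ± 3.69 to 31.8 ± 6.24, Nrxn3, a presynaptic neurexin, from 68.3 ± 3.3 to 47.3 ± 12.4, and the receptor phosphatase gene Ptprd from 46.5 ± 3.7 to 25.5 ± 9.47. Robo1, an axon guidance receptor, went from 44 ± 3.46 to 26 ± 5.94. The other 5 named by the same rule were the potassium channel partners Kcnip4 and Dpp6, the scaffold gene Magi2, Macrod2 and Ctnnd2. Of these 10 genes, 0 kept non-overlapping counts on the lists as deposited or at the stricter threshold, and 4 did with 36274 peaks per list. Genes of 500 kb or longer held 7.65% ± 0.217 of a Sham library's peaks and 5.94% ± 0.913 of a BCAS library's (exact permutation p = 0.0286, or 0.0571 without any 1 of the Sham libraries). The difference was -1.71 percentage points, and -0.878 (exact p = 0.0571) with regions of 0 Sham and 2 or more BCAS libraries left out before the lists were shortened, a setting chosen after the data were seen. Genes under 20 kb held 16.6% ± 0.257 and 18.8% ± 1.24 (exact permutation p = 0.0286), but the difference was 1.51 percentage points on the lists as deposited (exact p = 0.171) and 0.996 at the stricter threshold (exact p = 0.4). On the lists as deposited 41 genes had fewer peaks in every BCAS library, 21 of them among the 258, and at the stricter threshold 22 did, 19 of them among the 258. The count was 170 with 36274 peaks per list, and 399, 390, 432 or 493 without Sham 1, Sham 2, BCAS 1 or BCAS 4.

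**Figure D4:**
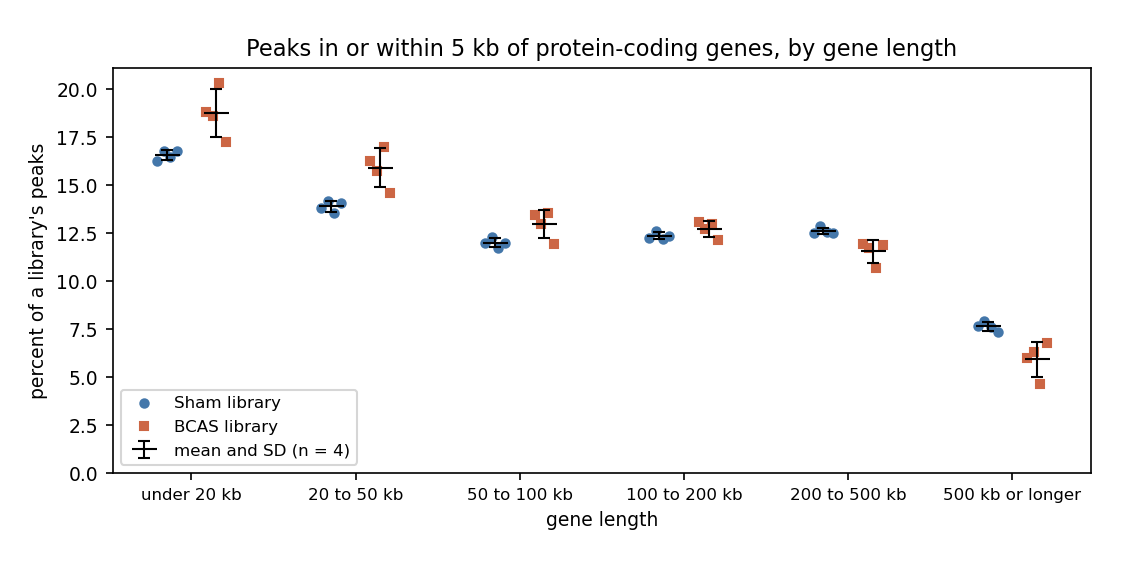
Percent of each library's 72548 peaks that lay in or within 5 kb of protein-coding genes (vertical axis), by gene length class, with points for libraries and bars for the mean and SD (n = 4). Genes of 500 kb or longer held 7.65% in Sham and 5.94% in BCAS.

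Direct-pathway medium spiny neuron genes, of the projection neurons that express the dopamine receptor gene Drd1, held 48 ± 3.74 peaks in BCAS and 66.8 ± 3.86 in Sham (SD, n = 4; exact permutation p = 0.0286, adjusted p = 0.0667). Of its 10 genes, only Eya1 was lower in every BCAS library (6.75 ± 0.957 against 11 ± 3.37), and Drd1 itself held 1.75 ± 0.5 against 1.5 ± 0.577 peaks. Ebf1, a transcription factor gene, held 11 ± 3.92 against 18 ± 4.32 peaks, and its counts overlapped between groups. On the lists as deposited the difference was -12.3 peaks (exact p = 0.229), at the stricter threshold -7.25 (exact p = 0.343) and with 36274 peaks per list -9.5 (exact p = 0.0571). Indirect-pathway genes held 50 ± 6.48 and 46.5 ± 2.38 peaks (exact p = 0.371), pan-striatal genes 170 ± 28.1 and 176 ± 16.4 (exact p = 0.8), and interneuron genes 8.5 ± 1.29 and 10.8 ± 1.71 (exact p = 0.143), BCAS first. The overlap of the indirect-pathway totals came from BCAS 4, with 41 peaks, against 50 to 56 in BCAS 1 to 3 and 44 to 49 in Sham libraries. Their higher BCAS mean came from 1 long gene, Ptprm, of 687644 bp, with 27 ± 4.55 peaks against 20.8 ± 2.22 in Sham. No other gene of that list had a higher mean in BCAS, and the median difference per gene was -0.25. Cortical excitatory neuron genes, a check on neighbouring tissue, held 34.3 ± 4.65 and 32 ± 0.816 (exact p = 0.429), with 1 of 14 higher in every BCAS library, Slc30a3 (1.75 ± 0.5 against 0). Dopamine and glutamate synapse genes held 183 ± 35.8 and 221 ± 18.2 (exact p = 0.0857), with 132 peaks in BCAS 3 and 185 to 212 in the other BCAS libraries. Among them Syt1, a synaptic vesicle calcium sensor, held 20.8 ± 2.63 against 28 ± 3.37 peaks, lower in every BCAS library. The gene ends of Pdyn, which encodes prodynorphin, and Gpr52 held a peak in 4 Sham libraries and 1 BCAS library. Those of Bcas1, a gene of the oligodendrocyte precursor list, held a peak in 4 Sham and 0 BCAS libraries. Over its whole window Bcas1 held 4.75 peaks on average in both groups. Over the 21 lists, 0 passed 0.05 after adjustment and 9 had an unadjusted exact p of 0.0286.

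Peak number, genome coverage and mean peak width overlapped between the groups. BCAS libraries held 92148 ± 13897 peaks and Sham libraries 83870 ± 12791 (SD, n = 4; exact permutation p = 0.4), covering 38.4 ± 1.96 and 36.2 ± 6.85 Mb (exact p = 0.6). Mean peak width was 422 ± 51.3 bp in BCAS and 430 ± 25.1 bp in Sham (exact p = 0.857). Gene ends held 18.2% ± 0.523 of BCAS and 17.4% ± 0.465 of Sham peaks (exact p = 0.0571, adjusted p = 0.171), and the difference was -0.0318 percentage points on the lists as deposited and -0.865 at the stricter threshold. Gene interiors held 45.5% ± 1.27 and 45.1% ± 1.08 (exact p = 0.657), with a difference of -0.0544 without BCAS 1, and the space between genes 36.3% ± 1.5 and 37.5% ± 0.966 (exact p = 0.286). Chromosome 7 held 5.07% ± 0.486 of BCAS and 4.31% ± 0.12 of Sham peaks, and chromosome 17 held 3.75% ± 0.234 and 3.21% ± 0.017. Chromosomes 3, 12, 18 and X held smaller shares in every BCAS library, and all 6 had an exact permutation p of 0.0286 and an adjusted p of 0.1. The share of bases in common averaged 0.533 between Sham libraries, 0.507 between BCAS libraries and 0.438 between groups. Pairs within groups exceeded pairs between groups by 0.0819 (one-sided exact permutation p = 0.0286, the smallest over 35 splits).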

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

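In 7 of 102 groups of 4 libraries, 1 library lay far from the other 3 of its group relative to their range, and chance alone does this in about 5% of groups. BCAS 2 covered 35.5 Mb, against 39.1 to 39.8 Mb in the other BCAS libraries. Sham 1 had a mean peak width of 468 bp, against 413 to 421 bp, and a background pileup of 2.52, against 1.52 to 1.62, in the other Sham libraries. At housekeeping genes BCAS 1 had 48 peaks, against 42 to 43. Sham 3 held 6.62% of its peaks on chromosome 3, against 6.32% to 6.35%, and 5.41% on chromosome 11, against 5.8% to 5.86%. BCAS 4 held 5.8% of its peaks on chromosome 10, against 5.62% to 5.64%. No explanation was weighed for these values.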

How the results depend on the processing

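Absence judged on the lists as deposited and the values for genes of 500 kb or longer were chosen after seeing the data. BCAS-specific regions numbered 3096 with 36274 peaks per list, and 5260 to 7069 under the other list, overlap and window settings or without 1 library 6058 to 8151. Sham-specific regions were fewer on the lists as deposited (662), at the stricter threshold (412), with 36274 peaks (642) and with absence judged on the lists as deposited (337), and numbered 1363 to 1920 without 1 library. Genes higher in BCAS numbered 859 to 1434 over list and window settings and 1255 to 1746 without 1 library. Genes lower in BCAS numbered 41 as deposited, 22 at the stricter threshold, 170 with 36274 peaks and 357 to 493 without 1 library. Gene ends with a listed peak in all BCAS and no Sham libraries numbered 208 to 306 over list and window settings, and the reverse 4 as deposited, 5 at the stricter threshold and 18 to 33 without 1 library. Counts rise when a library is left out because fewer libraries must meet the rule. Of the 1149 Sham-specific regions, only 337 had no peak in any BCAS list as deposited. For the others, shortening had removed a listed BCAS peak. The shortened lists ended at a -log10 q-value of 5.68, 2.46, 1.34 and 5.53 in Sham 1 to 4. In BCAS 1 to 4 they ended at 8.27, 4.52, 4.58 and 5.16. The cause of the other lower counts was not tested.

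The difference in gene-end share reversed on the lists as deposited (-0.0318) and at the stricter threshold (-0.865), and that in gene-interior share ranged from -0.0544 (BCAS 1) to 0.938 without 1 library and was 1.54 at the stricter threshold. Among lists with no call, the BCAS minus Sham difference reversed for pan-striatal (14.5 as deposited, 25 stricter, -16.3 to 5.67 without 1 library), interneuron (0.5 and 1), oligodendrocyte (7.5 and 5), precursor (3.75 and 6.75) and synapse genes (4, stricter). It reversed for astrocyte genes (12.5 as deposited, 12 stricter, 3 with 36274 peaks, 0.75 in gene bodies, 8 by nearest gene within 50 kb, -2.75 to 0.583 without 1 library) and for indirect-pathway genes with 36274 peaks (-0.75). The cause was not tested. The list count past adjustment was 0 under every setting, with 5 to 11 lists at an unadjusted p under 0.05 without 1 library. At an unadjusted p under 0.05, 6 chromosomes became 1 without any 1 Sham library and 12 without BCAS 4. The difference in share for genes of 500 kb or longer was -1.98 to -1.28 without 1 library, with an exact p of 0.0571 without any 1 Sham library. The 10 named higher genes all kept non-overlapping counts as deposited and at the stricter threshold and 9 did with 36274 peaks, and of the 10 named lower genes 0, 0 and 4 did, all with the direction kept. Of 10 named BCAS-specific regions 7, 10 and 10 kept their call, and of 10 Sham-specific regions 2, 6 and 5.

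Same-numbered libraries shared only a number: their deviations from the group means correlated at -0.125 to 0.139, and 1 of 4 Sham libraries correlated best with its own number. With the replicate number as a block, 1604 genes were higher and 604 lower in every pair, and no list or chromosome could pass because the smallest exact p was 0.125. The region counts of 5994 and 1149 are the same under this block by definition, so they give no check. The planned motif tests and windows based on transcription start sites were not run, for lack of sequence and strand. The rank cut sets the weakest peak of a shortened list, so a region absent from it may be open below that cut. Depth may also bear on which peaks are listed, which was not tested. Absence judged on the longer lists left 5260 BCAS-specific regions.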

Other observations

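Some families of genes with a shared symbol stem held more genes higher in BCAS than chance gives, with Tlr2, Tlr4 and Casp1 already counted in the NF-kappa-B list. Of 309 families, 3 passed for higher genes and 0 for lower genes, by a one-sided Fisher's exact test adjusted over families. Of 11 Toll-like receptor genes, 7 were higher (exact test, adjusted p = 0.000272), among them Tlr7, a sensor of single-stranded RNA, with 0.25 ± 0.5 peaks in Sham and 4 in each BCAS library, and Tlr13, with 0 and 3.25 ± 0.5 (SD, n = 4). Of 10 caspase genes, 5 were higher (exact test, adjusted p = 0.0286): Casp1, Casp4, Casp8, Casp9 and Casp12. Casp1, Casp4 and Casp12 are neighbours on chromosome 9 and can share peaks. Of 84 genes with a Cd symbol, 22 were higher (exact test, adjusted p = 9.09e-06), among them Cd84 (0.5 ± 0.577 against 5.25 ± 0.5 peaks), Cd86 (2.5 ± 0.577 against 6.5 ± 1.29) and Cd33 (0 against 1.5 ± 0.577). The 22 also held the B- and T-cell genes Cd79a (1 against 2.25 ± 0.5), Cd22 (0 against 1.25 ± 0.5), Cd3d (0 against 1) and Cd6 (2.75 ± 0.5 against 5 ± 0.816). Of these 22, 5 Cd300 and 3 Cd200r genes lie near one another and can share peaks. With members less than 100 kb apart counted once, by the first on the chromosome, 14 of 68 Cd genes (exact test, adjusted p = 0.026) and 7 of 10 Toll-like receptor genes (adjusted p = 0.00021) were higher, and for the caspases, with 3 of 8, the adjusted p was 0.755. These tests also take genes as independent units, although all calls came from the same libraries. These families, genes and tests were chosen after their values were seen.

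Of the tests in this part, those on other splits and on 36274 peaks per list had been planned, with their bounds written after the values were seen, those on blood leukocytes and on gained regions were set out before their own results, the later test on gained regions being added after the value of the first was seen, and the others were chosen after. The bound of the test on neuronal nuclei was also written before its result, but its gene set and its margin were changed afterwards, as told with its values.

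The counts of regions and genes argue against chance as their source, but a rank of 1 in 35 splits cannot exclude it. Of 35 splits of the 8 libraries, 1, the real one, gave as many regions (7143, highest other 666), genes (1461, highest other 235) and gene ends (272, highest other 28). These are totals of both directions. The 12 gene ends lower in BCAS do not stand out by themselves, since another split gave 22 in 1 direction.

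Microglial genes had more peaks in BCAS. With every list shortened to 36274 peaks, the lowest BCAS library still held 34 more peaks at homeostatic genes than the highest Sham library. This result argues against list length, but shortening by rank does not equalise read depth, so depth was not tested. At 6 genes of the homeostatic list taken as absent from blood leukocytes the gap was 11 peaks, which argues against blood leukocytes as the whole source. Of these 6, 4 were higher in every BCAS library, while Gpr34 overlapped and Sall1 held 2.25 peaks in both groups. A set of 9 lymphocyte and granulocyte genes held 4.75 ± 1.71 against 2 peaks and also separated the groups, by 1 peak. A set of 4 border macrophage genes held 6.5 ± 2.38 peaks in BCAS and 4 ± 0.816 in Sham. Its totals overlapped between the groups, which does not exclude a part for these cells. A larger share of microglial nuclei and wider opening within each cell both stay open, since bulk lists do not divide them, and the stenosis itself, as the biological difference between the groups, was not separated from either.

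Genes of 500 kb or longer held a smaller share of peaks in BCAS: the highest BCAS share minus the lowest Sham share was -0.602 percentage points, -0.458 on the lists as deposited and -0.26 with regions of all BCAS and no Sham libraries left out, which argues against list shortening and against those regions as the whole cause. Displacement by regions gained in fewer BCAS libraries cannot be told apart from a loss in these genes: with regions of 0 Sham and 2 or more BCAS libraries left out before the lists were shortened this value was 0.0366, with shares of 7.45% ± 0.211 in Sham and 6.57% ± 0.791 in BCAS (SD, n = 4; exact p = 0.0571), and with 1, 3 or 4 or more it was -0.141, -0.0559 and -0.136. A smaller share of neuronal nuclei cannot be told apart from a change within neurons, which was not tested: at 16 medium spiny neuron genes under 200 kb the highest BCAS library held 8 more peaks than the lowest Sham library, with means of 58.5 ± 6.56 and 62.5 ± 3.87 (SD, n = 4). By the bound first written, of 0 or above, this value, and the value of 9 for the 17 genes first listed, would have counted against fewer neurons; Rarb, of 651493 bp, was removed because it was too long for the set. A margin of 2 SD from the 48.5 peaks that a fall like that of the long genes would give was then added, since a strong peak stays listed when fewer nuclei carry it, and the BCAS mean lay 1.52 SD above that value.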
